A study of Homo sapiens with 22 samples.

How the data were processed

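The series holds RNA-seq of 22 libraries from 4 human breast cancer cell lines, MCF7, MDA-MB-453, MDA-MB-468 and MCF7 shRB1-3, each with abemaciclib at 500 nM for 7 days or with DMSO. Per the labels total RNA was extracted with the Nucleospin RNA Plus kit and libraries were made with the NEBNext Ultra RNA kit. Whether poly(A) RNA was selected is not stated. The values analysed are counts per gene symbol, as deposited by the authors in 2 tables, 1 with 18 libraries and 20114 genes and 1 with the 4 MCF7 shRB1-3 libraries and 25435 genes, of which 18956 symbols are shared. All values are whole numbers and column totals differ, as unscaled counts have. Per the submitters' processing notes, reads were aligned with STAR to hg19. Versions, the counting program, the annotation and the strand setting are not stated. The table of 18 libraries holds 13 mitochondrially encoded genes and the other 0, so the tables were not made with the same annotation, and levels were tested between them only in the joined fit named below.

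Each line was fitted by itself with edgeR 4.0.16 under R 4.3.3: filterByExpr (minimum count 10, minimum total count 15), TMM scaling, a robust quasi-likelihood fit with treatment as the only term, and Benjamini-Hochberg adjusted p under 0.05 as the threshold for a call. Differences in drug effect between lines are the interaction of line and treatment in a fit of the libraries of both lines. MCF7 shRB1-3 was compared with MCF7 on the shared symbols, with both tables joined. Printed p-values are adjusted over all tested genes, or over all lists of a comparison, unless called unadjusted. SE is the log2 fold change divided by the square root of its quasi-likelihood F, SD is between libraries and n is the number of libraries. For genes with 1 to 3 counts in a group the ratio is given with a 95% counting interval, which covers counting error only. Genes at 0 counts are given without a fold.

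The labels do not state whether replicates are separate cultures, so the p-values measure only the spread between these samples. Replicate numbers were checked as pairs. Residuals of same-numbered libraries correlated in MCF7 (r = 0.17, 0.64 and 0.66), MDA-MB-453 (0.43, 0.50 and 0.58) and MDA-MB-468 (0.67, 0.62 and 0.81). Unlike numbers reached 0.15 in MCF7 and 0.39 in MDA-MB-453, so MCF7 pair 1 and MDA-MB-453 pairs 1 and 2 are unsure. A fit with the number as a block is given where it changes a call or moves a count by over 1.5 times. In MCF7 shRB1-3 the libraries share only a number, since 2 pairs cannot be judged (r = 0.37).

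Gene lists were written before the data were examined, as were the samples' groups, the comparisons, the tests, the panel and most alternatives. They cover DNA replication, mitosis, cyclins, CDKs and the RB pathway, histones, DNA methylation and Polycomb, AP-1, interferon, MHC class I, estrogen receptor targets, luminal and basal markers, secreted inflammatory factors, p53 targets, the BCL2 family, cholesterol synthesis, lysosome, stress response, ribosome biogenesis, oxidative phosphorylation, receptor tyrosine kinases, extracellular matrix, mitochondrially encoded genes, and fibroblast, leukocyte and endothelial markers (25 lists). Lists with at least 5 tested members were tested with camera from limma 3.58.1, 2-sided, with a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Members were also counted adjusted over the list alone. Overlaps of calls were tested with Fisher's exact test over 24 overlaps.

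Named genes follow a rule. For each drug comparison they are the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 5 CPM and every treated library beyond every DMSO library. To these come a panel of 16 genes, and up to 3 called members of a list in its majority direction and 1 in the other, at a mean of at least 1 CPM. For differences between lines they are the 4 highest and 4 lowest.

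Alternatives tried were DESeq2 size factors (RLE), no filter beyond 1 count, a filter of at least 1 CPM, the DESeq2 1.42.0 Wald test, leaving out each library, the replicate block, a log2 fold change of at least 1, and 1 fit of all 18 libraries. Further ones were added after the data were seen, summing MDA-MB-453 libraries 1 and 2, and leaving out genes with 3 counts or fewer in either table of the joined fits. Against TMM, scaling by library totals shifted the median log2 fold change in MDA-MB-453 by -0.12 and the difference of MDA-MB-468 and MDA-MB-453 by 0.14. No library was left out of the main results.

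The steps were tested on simulated counts with 200 genes changed by 1 log2 unit. Of these, 87.9% were recovered in MCF7, 84.5% in MDA-MB-453, 80.5% in MDA-MB-468 and 9.5% in MCF7 shRB1-3 (of whose calls 36.7% were false). In the differences between lines 49%, 60.5%, 65.5% and 7.0% were recovered for MDA-MB-468 minus MCF7, MDA-MB-468 minus MDA-MB-453, MDA-MB-453 minus MCF7 and MCF7 shRB1-3 minus MCF7, and 34.5% in the DMSO comparison. With replicate effects simulated, 0% were recovered without a block in MCF7, MDA-MB-453 and MDA-MB-468. With it 88.4%, 87.5% and 82.5% were (4.3%, 9.8% and 9.3% of calls false). Without it the real data gave 5942, 7024 and 599 calls, so the 0% does not hold for those fits. Of 20 unchanged lists 0 were called.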

Results

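RNA was sequenced from human breast cancer cell lines kept for 7 days with 500 nM abemaciclib, an inhibitor of the cyclin-dependent kinases CDK4 and CDK6, or with the solvent DMSO. MCF7 is an estrogen receptor positive line, MDA-MB-453 a line with amplified ERBB2, and MDA-MB-468 a triple-negative line known to lack functional RB1, the protein through which CDK4 and CDK6 drive entry into S phase. These lines had 3 libraries per treatment. MCF7 shRB1-3, with a short hairpin against RB1, had 2 and came in its own table. Library totals lay between 19005126 and 33243786 in MCF7, between 14915451 and 24755690 in MDA-MB-453, between 15474518 and 25148910 in MDA-MB-468, and between 8413314 and 21729205 in MCF7 shRB1-3. Levels below are CPM, counts scaled to the library total by TMM, mean ± SD over the n libraries of the group just named, and log2 fold changes are abemaciclib over DMSO ± SE unless another contrast is named. After a log2 fold change, padj is the p adjusted over all tested genes by edgeR.

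RB1 is the target of the hairpin. In the fit that joins both tables its DMSO level was 47.9 ± 1.296 CPM in MCF7 (n = 3) and 2.42 ± 0.625 CPM in MCF7 shRB1-3 (n = 2), a log2 fold change of -4.35 ± 0.27, padj = 1.93e-05. The MCF7 shRB1-3 DMSO libraries stood at 2.86 and 1.98 CPM and the MCF7 DMSO libraries between 47.1 and 49.4 CPM. With abemaciclib the MCF7 shRB1-3 libraries stood at 1.16 and 2.03 CPM. MDA-MB-468 held RB1 at 1.96 ± 0.0841 CPM in DMSO and 2.54 ± 0.425 CPM with abemaciclib, and MDA-MB-453 at 91.2 ± 6.15 and 84.5 ± 5.51 CPM (n = 3 each). In MCF7 RB1 fell with abemaciclib, from 44.98 ± 0.969 to 35.96 ± 2.31 CPM (log2 fold change -0.32 ± 0.09, padj = 0.0185). That call was lost without MCF7 DMSO 1 (adjusted p = 0.0579) and without MCF7 abemaciclib 2 (adjusted p = 0.0713).

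Beyond RB1, the joined DMSO comparison called 631 of 12561 genes, 353 higher and 278 lower in MCF7 shRB1-3. CDKN1A, which codes for the CDK inhibitor p21, was at 59.98 ± 6.92 CPM in MCF7 and 126 ± 56.6 CPM in MCF7 shRB1-3 (log2 fold change 1.07 ± 0.27, padj = 0.0565). It was called by DESeq2 (adjusted p = 0.00846) and with no filter (0.0354), and its log2 fold change was 1.47 without MCF7 shRB1-3 DMSO 1. Of the estrogen receptor targets 5 of 31 tested rose, 0 fell and 26 were not called (9 rose and 0 fell adjusted over the list alone, median 0.21, camera adjusted p = 0.00858, adjusted p = 0.991 with an estimated correlation). Of the replication-dependent histones 0 of 37 tested rose, 3 fell and 34 were not called (0 rose and 3 fell adjusted over the list alone, median -0.41, camera adjusted p = 0.0373, adjusted p = 0.991 with an estimated correlation). Table, batch and hairpin cannot be told apart here, because MCF7 shRB1-3 has its own table and no non-targeting hairpin is among the samples. The count was 378, 381 and 215 without MCF7 DMSO libraries 1, 2 and 3. Without 1 of the MCF7 shRB1-3 DMSO libraries that group keeps 1 library, so no count is given here. The estrogen receptor list was not called without MCF7 shRB1-3 DMSO 2 (adjusted p = 0.593), nor the histone list without MCF7 DMSO 2 (adjusted p = 0.0953) or without either hairpin library (adjusted p = 0.16 and 0.0965).

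The first comparison asks what 7 days of abemaciclib change in MCF7, a line with RB1. Most tested DNA replication and mitosis genes fell and most tested lysosome and extracellular matrix genes rose, though no list kept its call with an estimated correlation. CCND1, coding for cyclin D1, rose from 535 ± 27.3 to 1354 ± 77.8 CPM (log2 fold change 1.34 ± 0.10, padj = 1.17e-05), and CDK6 from 10.8 ± 4.62 to 37.5 ± 7.01 CPM (1.79 ± 0.27, padj = 6.26e-04). MCM2, a subunit of the replicative helicase, fell from 415 ± 30.01 to 158 ± 15.4 CPM (-1.39 ± 0.11, padj = 1.06e-05), and MKI67, coding for the proliferation marker Ki-67, from 745 ± 171 to 283 ± 73.3 CPM (-1.396 ± 0.21, padj = 6.36e-04). In all, 5942 of 12754 tested genes were called, 3019 higher and 2923 lower, of which 1087 and 580 changed at least 2-fold.

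The largest increases in MCF7 were of KLK5, a kallikrein protease (0.123 to 20.2 CPM, log2 fold change 7.43 ± 0.42, padj = 2.62e-06), SSTR3, a somatostatin receptor (6.298 ± 0.30), and GPNMB, a transmembrane glycoprotein of lysosomes and melanosomes (5.81 ± 0.23). They were followed by CYP26B1, which breaks down retinoic acid (9.87 to 243 CPM, 4.61 ± 0.26, padj = 3.19e-06), MACC1 (4.44 ± 0.27) and SLFN5 (4.41 ± 0.29). The largest decreases were of CA2, a carbonic anhydrase (10.2 to 0.267 CPM, -5.196 ± 0.25, padj = 1.10e-06), GP2 (-3.12 ± 0.35) and the histone gene HIST1H2BH (-2.73 ± 0.32). Next came the kinase gene PIM1 (-2.62 ± 0.24), the ephrin receptor gene EPHA3 (-2.42 ± 0.19) and HMGB2, coding for a chromatin protein (292 to 55.8 CPM, -2.39 ± 0.13, padj = 2.06e-06). Treated and DMSO libraries did not overlap in these 12, by the naming rule, or in other called genes named for MCF7.

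Within the cell cycle panel, E2F1, a transcription factor held back by RB1, fell in MCF7 (86.8 to 34.5 CPM, -1.33 ± 0.13, padj = 4.44e-05). So did CDK4 (-0.41 ± 0.11, padj = 0.0114), DNMT1, the maintenance DNA methyltransferase (-0.78 ± 0.15, padj = 0.00229), and CCNE2, coding for cyclin E2 (-1.09 ± 0.26, padj = 0.00757). The CCNE2 call was lost without MCF7 DMSO 3 (adjusted p = 0.0558). CCNE1 had a log2 fold change of 0.01 ± 0.31, padj = 0.977 and CDKN1A one of -0.14 ± 0.11, padj = 0.34, neither called. FOSL2 (0.46 ± 0.11, padj = 0.00747) and JUN (1.02 ± 0.14, padj = 3.82e-04), both AP-1 subunits, rose. So did the interferon-induced gene IFIT1 (1.65 to 4.04 CPM, 1.33 ± 0.36, padj = 0.0131, lost at adjusted p = 0.128 in 1 fit of all 18 libraries), the MHC class I gene HLA-B (0.81 ± 0.11, padj = 2.64e-04) and BCL2L1, coding for the survival protein BCL-XL (0.67 ± 0.08, padj = 1.78e-04).

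Among the lists for MCF7, 0 of 45 tested rose, 45 fell and 0 were not called for DNA replication (0 rose and 45 fell adjusted over the list alone, median log2 fold change -1.02, camera adjusted p = 7.18e-26, adjusted p = 0.313 with an estimated correlation). PRIM1, a primase subunit, fell by the most in that list (-2.15 ± 0.13, padj = 2.62e-06). For mitosis, 0 of 50 tested rose, 49 fell and 1 were not called (0 rose and 49 fell adjusted over the list alone, median -1.33, camera adjusted p = 5.67e-35, adjusted p = 0.313 with an estimated correlation). CCNA2, coding for cyclin A2, fell by the most there, at -2.02 ± 0.20. For cyclins, CDKs and the RB pathway, 6 of 26 tested rose, 15 fell and 5 were not called (6 rose and 15 fell adjusted over the list alone, median -0.37, camera adjusted p = 0.0195, adjusted p = 0.632 with an estimated correlation). Without MCF7 DMSO 3 the cyclin list was not called (adjusted p = 0.0721). DNA methylation and Polycomb genes (2 of 17 tested rose, 8 fell and 7 were not called, 2 rose and 9 fell adjusted over the list alone, median -0.43, camera adjusted p = 0.0314, adjusted p = 0.385 with an estimated correlation) included EZH2, a histone methyltransferase, at -1.07 ± 0.11, padj = 4.64e-05. That list was not called without MCF7 DMSO 3 (adjusted p = 0.0636) or without MCF7 abemaciclib 2 (adjusted p = 0.05). Of the histone genes 3 of 31 tested rose, 13 fell and 15 were not called (3 rose and 13 fell adjusted over the list alone, median -0.66, camera adjusted p = 0.0193, adjusted p = 0.632 with an estimated correlation). Without MCF7 DMSO 2 the histone list was not called (median -0.20, adjusted p = 0.0567). Ribosome biogenesis genes (0 of 30 tested rose, 11 fell and 19 were not called, 0 rose and 9 fell adjusted over the list alone, 1 and 16 with the block, median -0.20, camera adjusted p = 0.023, adjusted p = 0.632 with an estimated correlation) included FBL, the rRNA methyltransferase fibrillarin, at -0.89 ± 0.10, padj = 1.08e-04. Without MCF7 DMSO 3 that list was not called (adjusted p = 0.0635).

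Lists that went up in MCF7 included the extracellular matrix and TGF-beta targets, of which 20 of 27 tested rose, 3 fell and 4 were not called (20 rose and 3 fell adjusted over the list alone, median 0.91, camera adjusted p = 3.49e-08, adjusted p = 0.0628 with an estimated correlation). ITGB6, an integrin subunit, had a log2 fold change of 3.68 ± 0.37. The collagen genes COL12A1 and COL5A1 rose from 164 to 1409.9 and from 36.4 to 256 CPM (3.11 ± 0.23 and 2.82 ± 0.11), whereas TIMP3, an inhibitor of matrix proteases, fell (-2.29 ± 0.20). Of the lysosome genes 28 of 41 tested rose, 1 fell and 12 were not called (29 rose and 2 fell adjusted over the list alone, median 0.58, camera adjusted p = 9.13e-09, adjusted p = 0.426 with an estimated correlation). PSAP, a precursor of sphingolipid activators, rose from 497 to 1159.7 CPM. Of the basal and myoepithelial markers 14 of 19 tested rose, 0 fell and 5 were not called (14 rose and 0 fell adjusted over the list alone, median 0.94, camera adjusted p = 2.47e-06, adjusted p = 0.313 with an estimated correlation). LAMB3, a laminin subunit (3.66 ± 0.27), and the keratin KRT15 (2.84 ± 0.22) rose. KRT14 had 2 counts over the DMSO libraries and 514 over the treated ones, a ratio of 291, with a counting interval from 80.2 to 2412, and its call was lost without MCF7 DMSO 2 or 3 (adjusted p = 0.103 and 0.16). Of the estrogen receptor targets 18 of 31 tested rose, 4 fell and 9 were not called (19 rose and 6 fell adjusted over the list alone, median 0.56, camera adjusted p = 1.94e-04, adjusted p = 0.632 with an estimated correlation). KRT13 (3.84 ± 0.49), FHL2 (2.45 ± 0.26) and PDZK1 (2.43 ± 0.25) rose, while GFRA1, a receptor for GDNF, fell (-0.56 ± 0.15). Of the AP-1 subunits 8 of 18 tested rose, 0 fell and 10 were not called (8 rose and 0 fell adjusted over the list alone, 11 and 3 with the block). The AP-1 median was 0.42 (camera adjusted p = 0.0118, adjusted p = 0.493 with an estimated correlation). FOS rose from 2.66 to 34.3 CPM (3.66 ± 0.21).

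Other lists in MCF7 moved in both directions or missed the threshold. Of the interferon-stimulated genes 16 of 41 tested rose, 6 fell and 19 were not called (17 rose and 7 fell adjusted over the list alone, median 0.39, camera adjusted p = 0.24), with SAMD9 at 2.396 ± 0.38 and HERC5 at -1.97 ± 0.18. Of the MHC class I genes 8 of 21 tested rose, 1 fell and 12 were not called (8 rose and 1 fell adjusted over the list alone, median 0.18, camera adjusted p = 0.0879), with HLA-F at 2.66 ± 0.17, padj = 3.58e-06. Oxidative phosphorylation genes (3 of 45 tested rose, 15 fell and 27 were not called, 3 rose and 14 fell adjusted over the list alone, median -0.19) had a camera adjusted p of 0.081, which became 0.045 with the replicate block, 0.00431 without MCF7 DMSO 3 and 0.0247 without MCF7 abemaciclib 2. Of the stress response genes 6 of 28 tested rose, 0 fell and 22 were not called (10 and 1 with the block, camera adjusted p = 0.262, and 0.022 without MCF7 DMSO 2). None of the 13 mitochondrially encoded genes was called by edgeR in MCF7 (0 and 3 with the block, higher and lower). Their share of all counts was 4.92% ± 0.822 in DMSO and 4.302% ± 0.704 with abemaciclib (SD, n = 3 each).

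**Figure D1:**
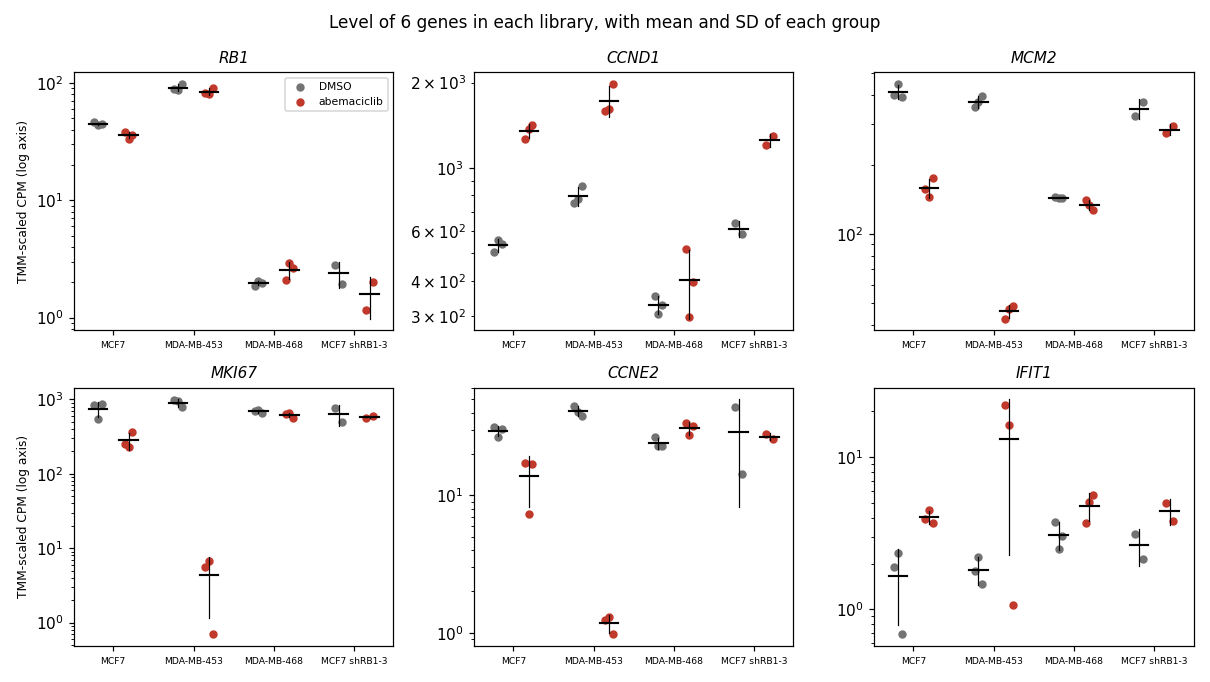
Level of 6 genes in each of the 22 libraries, as TMM-scaled CPM on a log axis against cell line, with DMSO in grey and abemaciclib in red. Horizontal bars are group means and vertical bars 1 SD. MKI67 went from a mean of 895 to 4.36 CPM in MDA-MB-453.

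The same question was put to MDA-MB-453, the other line with RB1 transcripts at a readily counted level. Most tested replication, mitosis and cholesterol synthesis genes fell and most tested lysosome, luminal and AP-1 genes rose. Of their lists only DNA replication kept its call with an estimated correlation. RRM2, a subunit of ribonucleotide reductase, fell from 393 ± 24.6 to 0.767 ± 0.294 CPM (log2 fold change -9.01 ± 0.16, padj = 3.28e-09), MKI67 from 895 ± 102 to 4.36 ± 3.23 CPM (-7.69 ± 0.64, padj = 2.75e-04) and MCM2 from 375 ± 21.4 to 46.1 ± 2.997 CPM (-3.03 ± 0.08, padj = 1.96e-08). PIP, the secreted prolactin-induced protein, rose from 11.7 ± 4.996 to 641 ± 12.5 CPM (5.76 ± 0.29, padj = 1.44e-05), and CCND1 from 797 ± 59.6 to 1726 ± 218 CPM (1.12 ± 0.10, padj = 1.68e-05). In all, 7024 of 11480 genes were called, 3465 higher and 3559 lower, with 777 and 1243 changed at least 2-fold. Libraries 1 and 2 of MDA-MB-453 lay closer to each other than to library 3 (chi-square per degree of freedom between libraries 2.49 against at least 15.1 in DMSO, 3.22 against at least 32.6 with abemaciclib). With libraries 1 and 2 of each treatment summed into 1, an alternative chosen after seeing the data, 5114 genes were called.

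Besides PIP, the largest increases in MDA-MB-453 were of AMELX, which codes for an enamel protein (0.131 to 18.1 CPM, log2 fold change 7.000 ± 0.46, padj = 9.19e-06) and UGT2B11, a steroid-conjugating enzyme (6.41 ± 0.40). Next came the mucin gene MUC2 (6.099 ± 0.20), the formyl peptide receptor gene FPR3 (5.39 ± 0.78) and SIGLEC15 (4.53 ± 0.15). The largest decreases besides RRM2 were of SPC25, a kinetochore gene (-8.51 ± 0.31), and PTTG1, coding for securin (-8.12 ± 0.29). MYBL2, a transcription factor of proliferating cells (791 to 2.88 CPM, -8.095 ± 0.45, padj = 3.79e-05), NMU and NEIL3 fell as well. NMU, coding for a neuropeptide, had 530 counts over the DMSO libraries and 1 over the treated ones, a ratio of 0.00138, with a counting interval from 3.49e-05 to 0.00773. NEIL3, a DNA glycosylase gene, had 687 and 3, a ratio of 0.003196, with a counting interval from 6.57e-04 to 0.00938. In these 12, by the naming rule, and in other called genes named here for MDA-MB-453 treated and DMSO libraries did not overlap.

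In the panel, CCNE2 fell in MDA-MB-453 from 40.9 to 1.17 CPM (-5.12 ± 0.14, padj = 2.32e-08), CCNE1 from 9.38 to 2.61 CPM (-1.84 ± 0.20, padj = 6.14e-05), E2F1 from 158 to 39.97 CPM (-1.98 ± 0.11, padj = 1.03e-06) and DNMT1 from 243 to 94.9 CPM (-1.36 ± 0.07, padj = 5.24e-07). JUN rose from 23.8 to 104 CPM (2.14 ± 0.22, padj = 1.89e-04), FOSL2 also rose (0.89 ± 0.11, padj = 1.32e-04), and BCL2L1 rose by less (0.30 ± 0.06, padj = 0.00245). CDK4 (-0.25 ± 0.07, padj = 0.0161) and CDKN1A (-0.29 ± 0.10, padj = 0.0302) fell slightly. The CDK4 call was lost without MDA-MB-453 abemaciclib 1 or 2 (adjusted p = 0.0693 and 0.0589) and with the libraries summed (0.139). The CDKN1A call was lost by DESeq2 (0.0927), with the libraries summed (0.133) and without any of the 6 libraries (DMSO 1, 2 and 3: adjusted p = 0.0596, 0.0961 and 0.0621, abemaciclib 1, 2 and 3: adjusted p = 0.0577, 0.0619 and 0.0544). CDK6 was low (2.63 to 1.59 CPM, -0.69 ± 0.75, padj = 0.458), and HLA-B (-0.18 ± 0.47, padj = 0.763) was not called.

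Of the mitosis genes in MDA-MB-453 1 of 50 tested rose, 49 fell and 0 were not called (1 rose and 49 fell adjusted over the list alone, median -4.37, camera adjusted p = 1.20e-71, adjusted p = 0.0833 with an estimated correlation). In DNA replication 0 of 45 tested rose, 44 fell and 1 were not called (0 rose and 44 fell adjusted over the list alone, median -1.99, camera adjusted p = 3.84e-61, adjusted p = 0.0215 with an estimated correlation). TYMS, coding for thymidylate synthase, fell from 70.7 to 1.01 CPM (-6.11 ± 0.13), and MCM10 fell too (-6.39 ± 0.27). For cyclins, CDKs and the RB pathway 4 of 28 tested rose, 18 fell and 6 were not called (4 rose and 18 fell adjusted over the list alone, median -0.85, camera adjusted p = 2.09e-10, adjusted p = 0.0215 with an estimated correlation). E2F2 (-5.83 ± 0.11) and E2F8 (-5.32 ± 0.22) fell. Of the DNA methylation and Polycomb genes 3 of 17 tested rose, 14 fell and 0 were not called (3 rose and 14 fell adjusted over the list alone, median -0.60, camera adjusted p = 2.82e-05, adjusted p = 0.0625 with an estimated correlation). HELLS, a chromatin remodeller (-3.65 ± 0.19), and EZH2 (-2.46 ± 0.09) fell. Of the cholesterol synthesis genes 1 of 24 tested rose, 19 fell and 4 were not called (1 rose and 20 fell adjusted over the list alone, median -0.94, camera adjusted p = 1.54e-07, adjusted p = 0.544 with an estimated correlation). ACAT2 fell from 79.2 to 17.1 CPM (-2.21 ± 0.08, padj = 8.15e-08) and INSIG1, a sterol-sensing regulator, from 202 to 44.8 CPM (-2.17 ± 0.15, padj = 1.21e-05), while DHCR24, an enzyme late in the pathway, rose (0.50 ± 0.10, padj = 0.00179).

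Going up in MDA-MB-453 were the lysosome genes, of which 30 of 38 tested rose, 5 fell and 3 were not called (30 rose and 5 fell adjusted over the list alone, median 0.60, camera adjusted p = 5.07e-09, adjusted p = 0.12 with an estimated correlation). ARSA, the gene for arylsulfatase A (1.96 ± 0.07), and SGSH (1.79 ± 0.09) rose. Of the luminal markers 15 of 25 tested rose, 1 fell and 9 were not called (15 rose and 1 fell adjusted over the list alone, median 0.36, camera adjusted p = 3.13e-04, adjusted p = 0.0833 with an estimated correlation). TSPAN1, a tetraspanin gene, rose from 136 to 556 CPM after PIP. Of the AP-1 subunits 10 of 16 tested rose, 2 fell and 4 were not called (10 rose and 2 fell adjusted over the list alone). The AP-1 median was 0.69 (camera adjusted p = 0.024, adjusted p = 0.217 with an estimated correlation). JUNB rose from 114 to 297 CPM (1.38 ± 0.12). Of the replication-dependent histones 18 of 34 tested rose, 6 fell and 10 were not called (18 rose and 6 fell adjusted over the list alone, median 0.83, camera adjusted p = 2.54e-04, adjusted p = 0.641 with an estimated correlation). HIST1H4H rose from 10.6 to 136 CPM (3.68 ± 0.30) and HIST1H2AI by 3.71 ± 0.31, and HIST2H2AC fell (-2.68 ± 0.31). Mitochondrially encoded genes took 5.29% ± 0.648 of counts in DMSO and 7.29% ± 0.7395 with abemaciclib (SD, n = 3 each). Of these genes 8 of 13 tested rose, 1 fell and 4 were not called (8 rose and 1 fell adjusted over the list alone, median 0.44, camera adjusted p = 0.098). That p was 0.00734 with the replicate block, 0.0163 without MDA-MB-453 DMSO 3 and 0.0211 without MDA-MB-453 abemaciclib 1.

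Interferon-stimulated genes differed between the treated MDA-MB-453 libraries. IFIT1 stood at 22.1, 16.2 and 1.07 CPM in abemaciclib libraries 1, 2 and 3 and between 1.47 and 2.22 CPM in DMSO (2.85 ± 1.09, padj = 0.0718). DESeq2 (adjusted p = 0.0135) and 1 fit of all 18 libraries (0.00221) called IFIT1. Of the list 8 of 35 tested rose, 3 fell and 24 were not called (6 rose and 3 fell adjusted over the list alone, median 0.25, camera adjusted p = 0.616). Without MDA-MB-453 abemaciclib 3 the IFIT1 log2 fold change was 3.405 (adjusted p = 2.64e-07) and the list median 0.65 (camera adjusted p = 0.00174). STAT1, a transcription factor of the interferon response, rose (1.23 ± 0.19, padj = 0.00143) and HERC5 fell (-2.37 ± 0.32, padj = 2.10e-04).

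Further lists in MDA-MB-453 missed the threshold. Of the basal markers 6 of 13 tested rose, 2 fell and 5 were not called (6 rose and 2 fell adjusted over the list alone, median 0.86), with a camera adjusted p of 0.183, 0.00982 with the block and 0.0269 without MDA-MB-453 abemaciclib 3. Of the ribosome biogenesis genes 3 of 30 tested rose, 17 fell and 10 were not called (3 rose and 17 fell adjusted over the list alone, median -0.25), with a p of 0.098, 0.0423 with the block and 0.0352 without MDA-MB-453 DMSO 2. Of the extracellular matrix genes 6 of 19 tested rose, 6 fell and 7 were not called (6 rose and 6 fell adjusted over the list alone, median 0.33), with a p of 0.101, and 0.0382 without MDA-MB-453 abemaciclib 3. In the stress response list 9 of 27 tested rose, 8 fell and 10 were not called (camera adjusted p = 0.993), where PHGDH, the first enzyme of serine synthesis, fell from 242 to 31.9 CPM (-2.92 ± 0.10, padj = 6.47e-08) and SESN2 rose (1.45 ± 0.14, padj = 3.61e-05).

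MDA-MB-468 has next to no RB1 transcript, and the comparison asks what the drug does in such a line. COL13A1, COL15A1, VIM and DDIT4 rose and EHF, S100A7 and S100A8 fell, whereas the replication and mitosis lists had medians of 0.11 and -0.06. MKI67 was at 690.5 ± 33.8 CPM in DMSO and 617 ± 46.6 CPM with abemaciclib (log2 fold change -0.16 ± 0.10, padj = 0.368). MCM2 was at 143 ± 0.706 CPM in DMSO and 133 ± 6.54 CPM with abemaciclib (-0.11 ± 0.08, padj = 0.469) and CCND1 at 329.9 ± 23.8 CPM in DMSO and 404 ± 109 CPM with abemaciclib (0.29 ± 0.18, padj = 0.39), none of them called. CDKN1A rose from 11.7 ± 0.932 to 29.5 ± 9.198 CPM (1.34 ± 0.22, padj = 0.0224). In all, 599 of 12041 genes were called, 279 higher and 320 lower, and 3263 with the replicate block, including all 599.

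The largest increases in MDA-MB-468 were of MYH15, a myosin gene (0.539 to 13.7 CPM, log2 fold change 4.66 ± 0.74, padj = 0.0203) and the collagen gene COL13A1 (3.08 ± 0.66). They were followed by OLFML3 (2.86 ± 0.59), GFPT2, an enzyme of the hexosamine pathway (2.67 ± 0.42), LAMA3, a laminin subunit (2.495 ± 0.47), and the collagen gene COL15A1 (2.403 ± 0.48). The largest decreases were of GABRP, a GABA receptor subunit (10.7 to 0.428 CPM, -4.57 ± 0.60, padj = 0.0116), and IGFBP5, an insulin-like growth factor binding protein (312 to 38.7 CPM, -3.005 ± 0.42, padj = 0.0142). Next came NDRG2 (-2.87 ± 0.34), the calcium-binding S100A7 (-2.84 ± 0.46) and S100A8 (-2.82 ± 0.37), and CES1, a carboxylesterase (-2.62 ± 0.24). Treated and DMSO libraries overlapped in none of the 599 calls. Without a block most of these calls need all 3 DMSO libraries, but leaving 1 out also parts a pair, which may itself lose calls. Of the 22 called genes named for MDA-MB-468, 9, 2 and 4 kept their call without DMSO libraries 1, 2 and 3, and 18, 21 and 18 without abemaciclib libraries 1, 2 and 3. Over all genes the counts were 85, 8 and 41 without DMSO 1, 2 and 3, and 271 and 1413 without abemaciclib 1 and 3.

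For CDKN1A the MDA-MB-468 call was lost without DMSO 1, 2 or 3 (adjusted p = 0.071, 0.112 and 0.0988). HLA-B (-0.46 ± 0.11, padj = 0.0607) was called with the replicate block (adjusted p = 7.81e-04), by DESeq2 (0.00976) and without abemaciclib 3 (adjusted p = 0.0111). CDK4 was called by the first and last (0.29 ± 0.09, padj = 0.0917, then 0.0102 and 0.0276). With the block alone, CCNE1 (0.43 ± 0.21, padj = 0.265, then 0.0368), CCNE2 (0.36 ± 0.12, padj = 0.124, then 0.012), DNMT1 (0.22 ± 0.14, padj = 0.387, then 0.0482), FOSL2 (-0.21 ± 0.17, padj = 0.499, then 0.0415) and IFIT1 (0.64 ± 0.24, padj = 0.153, then 0.0409) passed. E2F1 (0.12 ± 0.10, padj = 0.508), CDK6 (0.02 ± 0.16, padj = 0.95), JUN (0.32 ± 0.39, padj = 0.674) and BCL2L1 (0.11 ± 0.13, padj = 0.662) did not.

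Counts with the block are of members that rose and fell. Of the stress response genes in MDA-MB-468 6 of 28 tested rose, 0 fell and 22 were not called (11 rose and 0 fell adjusted over the list alone, 14 and 2 with the block, median 0.46, camera adjusted p = 2.13e-05, adjusted p = 0.246 with an estimated correlation). DDIT4 (167 to 350.4 CPM), SLC3A2, a subunit of amino acid exchangers (329.6 to 528 CPM), and TRIB3 (166 to 265 CPM) rose. All of these gene calls were lost in 1 fit of all 18 libraries. Of the luminal markers 1 of 24 tested rose, 3 fell and 20 were not called (1 rose and 7 fell adjusted over the list alone, 3 and 12 with the block, median -0.30, camera adjusted p = 0.00206, adjusted p = 0.246 with an estimated correlation). The epithelial transcription factor gene EHF fell (-1.21 ± 0.17). Of the basal markers 2 of 24 tested rose, 0 fell and 22 were not called (8 rose and 1 fell adjusted over the list alone, 14 and 3 with the block, median 0.40, camera adjusted p = 0.0095, adjusted p = 0.595 with an estimated correlation). The called members were LAMA3 and the intermediate filament gene VIM (1.75 ± 0.21). Of the secreted inflammatory factors 3 of 19 tested rose, 2 fell and 14 were not called (6 rose and 2 fell adjusted over the list alone, 10 and 4 with the block, median 0.45, camera adjusted p = 0.0412, adjusted p = 0.598 with an estimated correlation). IL8, a neutrophil chemokine (2.296 ± 0.46), PLAT, tissue plasminogen activator (2.14 ± 0.18), and GDF15 (1.87 ± 0.28) rose. Of the ribosome biogenesis genes 1 of 30 tested rose, 0 fell and 29 were not called (4 rose and 0 fell adjusted over the list alone, 13 and 0 with the block, median 0.22, camera adjusted p = 3.30e-04, adjusted p = 0.595 with an estimated correlation). Of cyclins, CDKs and the RB pathway 2 of 28 tested rose, 1 fell and 25 were not called (5 rose and 1 fell adjusted over the list alone, 7 and 2 with the block, median 0.17, camera adjusted p = 0.0219, adjusted p = 0.595 with an estimated correlation). Mitochondrially encoded genes took 3.53% ± 0.274 of counts in DMSO and 5.25% ± 1.58 with abemaciclib (SD, n = 3 each). Of their list 0 of 13 tested rose, 0 fell and 13 were not called (5 rose and 0 fell adjusted over the list alone, 11 and 0 with the block, median 0.67, camera adjusted p = 3.69e-05, adjusted p = 0.595 with an estimated correlation). The basal list was not called without abemaciclib 1 (adjusted p = 0.0575), the cyclin list without abemaciclib 1 or 3 (0.0575 and 0.098), and the inflammatory list without DMSO 2 or abemaciclib 3 (0.0594 and 0.158).

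Of the DNA replication genes in MDA-MB-468 1 of 45 tested rose, 0 fell and 44 were not called (1 rose and 0 fell adjusted over the list alone, 8 and 2 with the block, median log2 fold change 0.11, camera adjusted p = 0.0608). Of the mitosis genes 0 of 50 tested rose, 0 fell and 50 were not called (3 and 6 with the block, median -0.06, camera adjusted p = 0.303). The DNA replication list was called, with a positive median, without DMSO 2 (adjusted p = 0.0304) and without abemaciclib 3 (0.049). Of the histones 0 of 21 tested rose, 1 fell and 20 were not called (0 and 2 with the block, median -0.24, camera adjusted p = 0.0723), a list called without DMSO 2 (adjusted p = 0.0287) and without abemaciclib 2 (0.00731). Of the lysosome genes 4 of 42 tested rose, 0 fell and 38 were not called (13 and 5 with the block, median 0.08, camera adjusted p = 0.11, and 0.0326 without abemaciclib 1). Of the interferon-stimulated genes 3 of 44 tested rose, 1 fell and 40 were not called (6 and 9 with the block, median 0.03, camera adjusted p = 0.848).

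**Figure D2:**
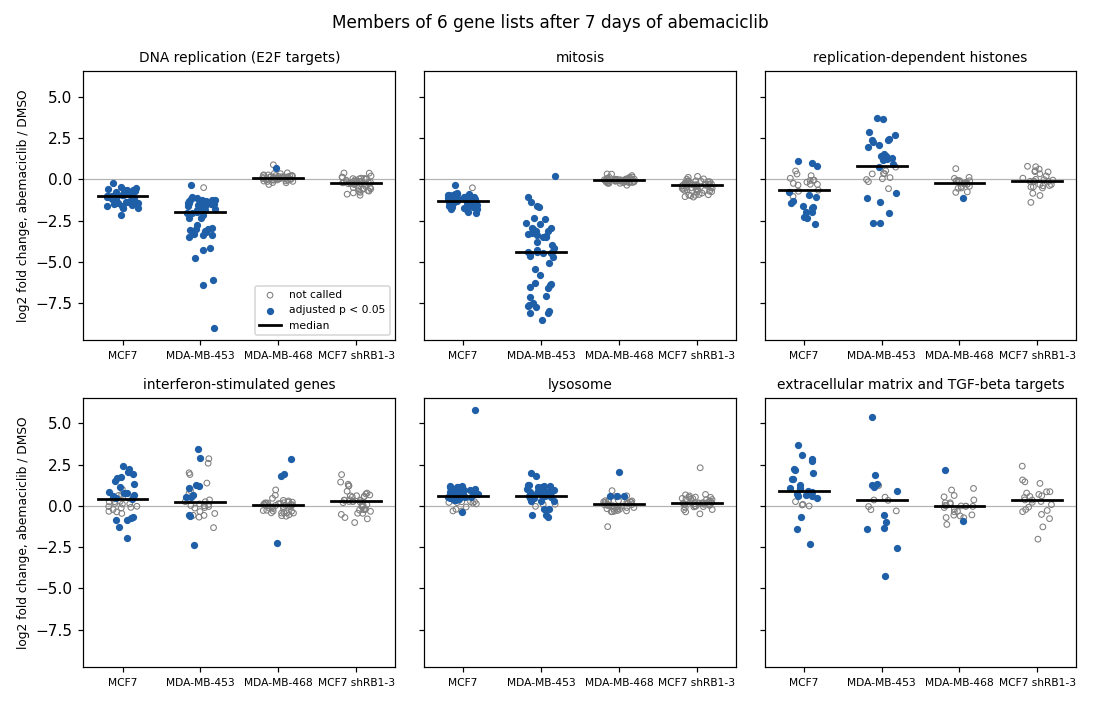
Log2 fold change, abemaciclib over DMSO, of each tested member of 6 gene lists in the 4 cell lines. Filled points passed an adjusted p of 0.05, open points did not, and bars are list medians. The mitosis medians are -1.33 in MCF7, -4.37 in MDA-MB-453, -0.06 in MDA-MB-468 and -0.37 in MCF7 shRB1-3.

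MCF7 shRB1-3 carries the hairpin against RB1, and the comparison asks what the drug does in that line. CCND1 was at 612 ± 40.6 CPM in DMSO and 1250.5 ± 68.2 CPM with abemaciclib (log2 fold change 1.03 ± 0.19, padj = 0.443) and CDK6 at 11.5 ± 1.89 CPM in DMSO and 26.4 ± 0.442 CPM with abemaciclib (1.203 ± 0.26, padj = 0.478), above DMSO in both treated libraries but not called (n = 2 each). MCM2 was at 349 ± 34.8 CPM in DMSO and 284 ± 15.1 CPM with abemaciclib (-0.30 ± 0.20, padj = 0.7). E2F1 was at 62.3 ± 17.1 CPM in DMSO and 56.3 ± 0.437 CPM with abemaciclib (-0.15 ± 0.26, padj = 0.89) and MKI67 at 635 ± 192 CPM in DMSO and 576 ± 22.7 CPM with abemaciclib (-0.14 ± 0.25, padj = 0.892). CCNE2 (-0.10 ± 0.49, padj = 0.965), CDKN1A (-0.63 ± 0.33, padj = 0.637), JUN (0.40 ± 0.38, padj = 0.78), IFIT1 (0.77 ± 0.40, padj = 0.637) and BCL2L1 (0.05 ± 0.31, padj = 0.971) were not called either. Leaving out 1 DMSO library keeps 1 in that group, so only log2 fold changes are given here for such fits. Without DMSO 1 they were -1.03 for CDKN1A and 1.07 for IFIT1. Without DMSO 2 they were 1.09 for JUN, -0.44 for MKI67 and 0.53 for BCL2L1. Of 13239 genes edgeR called 0, the smallest adjusted p being 0.342, with 1103 genes at an unadjusted p under 0.05 where chance alone gives about 662. DESeq2 called 64, and edgeR 21 without the filter on low counts. CCND1 was called by DESeq2 (adjusted p = 0.00487). The CCND1 log2 fold change was 1.10 without DMSO 1 and 0.94 without DMSO 2, and that of CDK6 1.37 and 1.02. That of CCNE2 was 0.90 without DMSO 1 and -0.73 without DMSO 2. The libraries of DMSO lay far apart (chi-square per degree of freedom 75.95, against 13.1 between those with abemaciclib).

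In MCF7 shRB1-3 the mitosis and DNA replication lists had medians of -0.37 and -0.21 (camera adjusted p = 5.29e-09 and 0.003). Both had adjusted p = 0.705 with an estimated correlation and 0 members called over all genes or adjusted over the list alone. Without DMSO 1 these medians were -0.08 (adjusted p = 0.32) and -0.01 (0.446). Extracellular matrix genes (median 0.35, 2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.003) shifted up. Lysosome genes (median 0.18, 1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.00436) did too. Each had adjusted p = 0.705 with an estimated correlation. Both calls were lost without DMSO 1 (adjusted p = 0.525 and 0.32). Also called were the interferon-stimulated genes (median 0.26, camera adjusted p = 0.0207), luminal markers (-0.19, 0.0204) and p53 targets (-0.29, 0.0207). All 3 had adjusted p = 0.705 with an estimated correlation. Each of the 3 was lost without DMSO 2 (adjusted p = 0.0985, 0.998 and 0.582), the interferon list also without DMSO 1 (0.103) and the luminal list without abemaciclib 1 (0.0599).

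The interaction of line and treatment tests whether the drug effect itself differs, first between MDA-MB-468 and MCF7. The fall of cell cycle genes in MCF7 was not seen in MDA-MB-468, and the difference itself passed the test for MCM2 (difference of log2 fold changes, MDA-MB-468 minus MCF7, 1.26 ± 0.13, padj = 2.75e-05), E2F1 (1.43 ± 0.17, padj = 8.03e-05) and MKI67 (1.21 ± 0.26, padj = 0.00385). CCND1 (-1.07 ± 0.22, padj = 0.00291), CDK6 (-1.79 ± 0.35, padj = 0.00257) and HLA-B (-1.29 ± 0.15, padj = 6.05e-05) differed the other way. Of the DNA replication genes 43 of 45 were higher in the difference and 0 lower (43 and 0 adjusted over the list alone). The DNA replication median was 1.204 (camera adjusted p = 3.50e-33, adjusted p = 0.191 with an estimated correlation). Of the mitosis genes 48 of 50 were higher and 0 lower (49 and 0 adjusted over the list alone). The mitosis median was 1.21 (camera adjusted p = 1.92e-35, adjusted p = 0.191 with an estimated correlation). Over all genes 3908 of 13473 differed, 1858 with a higher and 2050 with a lower value in MDA-MB-468, and 6060 with the replicate block, JUN among them (-0.72 ± 0.47, padj = 0.281, then 8.56e-04).

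At the top of this difference stood genes near 0 counts in a group, so no fold is given. ACKR3, TMEM121, BCHE and CPPED1 were listed at 0 counts in the MDA-MB-468 DMSO libraries and at 16, 5, 3 and 8 in the treated ones, and had 2436, 1226, 1166 and 1323 counts in MCF7 DMSO. At the other end CEACAM1, S100A8 and KRT14 had 0, 1 and 2 counts in MCF7 DMSO. KLK5, which rose in MCF7, was at 348 and 252 CPM in MDA-MB-468 (difference -7.91 ± 0.54, padj = 2.31e-06). Calls lost without a single library were those of ACKR3 (adjusted p = 0.0673 without MDA-MB-468 DMSO 3 and 0.0548 without MDA-MB-468 abemaciclib 2), TMEM121 (adjusted p = 0.0766 without MDA-MB-468 abemaciclib 2) and CPPED1 (adjusted p = 0.0556 without MDA-MB-468 DMSO 3 and 0.0533 without MDA-MB-468 abemaciclib 1). BCHE had adjusted p = 0.0588 and 0.0596 without MCF7 DMSO 1 and 2, 0.0602 without MCF7 abemaciclib 1, 0.0663, 0.0719 and 0.0921 without MDA-MB-468 DMSO 1, 2 and 3 and 0.201 and 0.0588 without MDA-MB-468 abemaciclib 2 and 3. KRT14 had adjusted p = 0.0608, 0.0506 and 0.105 without MCF7 DMSO 1, 2 and 3, 0.0605 and 0.0551 without MDA-MB-468 DMSO 1 and 3 and 0.0623 and 0.0683 without MDA-MB-468 abemaciclib 2 and 3.

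MDA-MB-468 differed from MDA-MB-453 in 4875 of 12804 genes, 2357 with a higher and 2518 with a lower value in MDA-MB-468. RRM2 was at 323 and 360.0 CPM in MDA-MB-468, which gave a difference of 9.11 ± 0.19, padj = 3.85e-12, and SPC25 one of 8.36 ± 0.41, padj = 1.21e-08. NMU and NEIL3 also led, with 1 and 3 counts in treated MDA-MB-453. CCNE2 (5.42 ± 0.19, padj = 6.77e-10), MKI67 (7.46 ± 0.55, padj = 1.05e-06) and MCM2 (2.86 ± 0.11, padj = 1.08e-09) differed in the same direction. Lower in the difference were ITGB6 (-5.52 ± 0.95, padj = 6.98e-04), PLCE1, a phospholipase gene (-4.13 ± 0.90, padj = 0.00327), RHOU, a Rho-family GTPase (-4.88 ± 0.32, padj = 1.79e-07), and GABRA3, with 2 counts in MDA-MB-453 DMSO. Of the mitosis genes 49 of 50 were higher and 0 lower (49 and 1 adjusted over the list alone). The mitosis median was 4.297 (camera adjusted p = 3.66e-130, adjusted p = 0.00335 with an estimated correlation), and of the cholesterol synthesis genes 18 of 25 were higher and 1 lower (18 and 1 adjusted over the list alone). The cholesterol median was 0.87 (camera adjusted p = 1.68e-06, adjusted p = 0.461 with an estimated correlation). With the block RB1 (0.43 ± 0.18, padj = 0.0704, then 0.0384, also adjusted p = 0.0353 without MDA-MB-453 abemaciclib 3 and 0.0178 without MDA-MB-468 abemaciclib 1), BCL2L1 (-0.25 ± 0.15, padj = 0.201, then 0.0329, also adjusted p = 0.0215 without MDA-MB-468 abemaciclib 1) and the AP-1 list (median -0.58, camera adjusted p = 0.156, then 0.0358) were called.

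MDA-MB-453 and MCF7, both with RB1 transcript, differed in 4304 of 13061 genes, 1938 with a higher and 2366 with a lower value in MDA-MB-453. The fall of MKI67 was larger in MDA-MB-453 (difference -6.29 ± 0.65, padj = 6.64e-05), as was that of RRM2 (-7.56 ± 0.33, padj = 1.21e-08) and MCM2 (-1.64 ± 0.13, padj = 6.26e-07), and JUN rose by more (1.12 ± 0.27, padj = 0.00638). UGT2B11 (8.003 ± 0.57, padj = 3.99e-07), UGT2B15, another steroid-conjugating enzyme (5.02 ± 0.64, padj = 7.21e-05), and MUC2 (5.45 ± 0.81, padj = 1.69e-04) led the higher side with CYP4F11, which was listed at 0 counts in MDA-MB-453 DMSO and 8 with the drug. HSPB8 and GPC6 were listed at 0 counts in treated MDA-MB-453, and NMU at 1. Of the mitosis genes 1 of 50 were higher and 47 lower (1 and 47 adjusted over the list alone). The mitosis median was -2.96 (camera adjusted p = 1.17e-65, adjusted p = 0.141 with an estimated correlation). Of the histones 23 of 37 were higher and 0 lower (24 and 2 adjusted over the list alone). The histone median was 1.27 (camera adjusted p = 5.66e-09, adjusted p = 0.277 with an estimated correlation). With the block CCND1 (-0.23 ± 0.14, padj = 0.231, then 0.0455), FOSL2 (0.43 ± 0.16, padj = 0.0584, then 0.00383, by DESeq2 0.0495, also adjusted p = 0.0153 without MCF7 DMSO 1 and 0.00901 without MDA-MB-453 abemaciclib 3) and HLA-B (-0.99 ± 0.44, padj = 0.109, then 0.0468, also adjusted p = 0.0304 without MDA-MB-453 abemaciclib 3) were called. The CYP4F11 call was lost without MDA-MB-453 DMSO 2 (adjusted p = 0.0509), DMSO 3 (0.0542) or abemaciclib library 1 (0.112).

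The drug effect in MCF7 shRB1-3 minus that in MCF7 differed for 462 of 12916 genes, 146 higher and 316 lower, and for 791 with the replicate block. A table or batch effect that is alike in both treatments on the log scale cancels in this difference. A drug response that depends on batch, or on carrying any hairpin, cannot be told apart from an effect of lower RB1. MCM2 (1.07 ± 0.19, padj = 0.0147) and E2F1 (1.16 ± 0.26, padj = 0.035) differed, MKI67 (1.23 ± 0.36, padj = 0.086) and CCND1 (-0.33 ± 0.18, padj = 0.346) were not called. NRM, a nuclear envelope gene (1.93 ± 0.36, padj = 0.0183), RIBC2 (1.79 ± 0.33, padj = 0.0175), CNIH2 (1.75 ± 0.36, padj = 0.0239) and DMC1, a recombinase gene (1.74 ± 0.34, padj = 0.0198), led the higher side. KLK5 (-4.34 ± 0.89, padj = 0.0239), SSTR3 (-3.72 ± 0.67, padj = 0.0151), CLCA2 (-3.66 ± 0.36, padj = 0.00128) and GPNMB (-3.500 ± 0.43, padj = 0.00345) led the lower side. Of the DNA replication genes 13 of 45 were higher and 0 lower (32 and 0 adjusted over the list alone). The DNA replication median was 0.86 (camera adjusted p = 5.29e-26, adjusted p = 0.245 with an estimated correlation), and of the mitosis genes 9 of 50 were higher and 0 lower (23 and 0 adjusted over the list alone, 22 and 0 with the block, median 0.83, camera adjusted p = 2.39e-23, adjusted p = 0.341 with an estimated correlation). The count was 115 and 269 without MCF7 DMSO libraries 1 and 2, and 110, 192 and 280 without MCF7 abemaciclib libraries 1, 2 and 3. It was 2103 and 1831 without MCF7 shRB1-3 DMSO libraries 1 and 2 (48.8% and 61.4% of them higher, against 31.6% with all libraries), and 14 and 36 without its abemaciclib libraries 1 and 2. Single libraries also ended the calls of MCM2 (adjusted p = 0.0563 without MCF7 abemaciclib 1 and 0.0862 and 0.0742 without MCF7 shRB1-3 abemaciclib 1 and 2) and E2F1 (adjusted p = 0.0994, 0.0759 and 0.0533 without MCF7 DMSO 1, 2 and 3, 0.0959 and 0.0798 without MCF7 abemaciclib 1 and 2 and 0.173 and 0.111 without MCF7 shRB1-3 abemaciclib 1 and 2). The same held for NRM (adjusted p = 0.0538 without MCF7 DMSO 1, 0.058 without MCF7 abemaciclib 1 and 0.112 and 0.0796 without MCF7 shRB1-3 abemaciclib 1 and 2) and RIBC2 (adjusted p = 0.0517 without MCF7 DMSO 1, 0.0567 without MCF7 abemaciclib 1 and 0.0524 and 0.0773 without MCF7 shRB1-3 abemaciclib 1 and 2). So it did for CNIH2 (adjusted p = 0.0738 and 0.0566 without MCF7 DMSO 1 and 2, 0.0714 and 0.0624 without MCF7 abemaciclib 1 and 2 and 0.168 and 0.069 without MCF7 shRB1-3 abemaciclib 1 and 2) and DMC1 (adjusted p = 0.0595 without MCF7 DMSO 1, 0.0566 without MCF7 abemaciclib 1 and 0.123 and 0.075 without MCF7 shRB1-3 abemaciclib 1 and 2). It held for KLK5 (adjusted p = 0.0557 without MCF7 DMSO 1, 0.0563 without MCF7 abemaciclib 1, 0.104 without MCF7 shRB1-3 DMSO 2 and 0.0955 and 0.0776 without MCF7 shRB1-3 abemaciclib 1 and 2) and SSTR3 (adjusted p = 0.0527 without MCF7 DMSO 1, 0.244 without MCF7 shRB1-3 DMSO 2 and 0.112 and 0.0773 without MCF7 shRB1-3 abemaciclib 1 and 2), but not for CLCA2 or GPNMB. MKI67 was called by DESeq2, with the replicate block or without MCF7 abemaciclib 3 (adjusted p = 0.0205, 0.0233 and 0.0496). DESeq2 and the block also called DNMT1 (0.86 ± 0.26, padj = 0.0964, then 0.0349 and 0.0388). Both called HLA-B (-0.71 ± 0.22, padj = 0.112, then 0.0413 and 0.0485). Without MCF7 abemaciclib 3 DNMT1 had adjusted p = 0.0492. This block pairs MCF7 shRB1-3 libraries that share only a number, so its 791 calls rest on unjudged pairs.

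Shared calls between lines were counted per direction among the genes tested in both, with Fisher's exact test, one-sided for an excess, over 24 overlaps. MCF7 and MDA-MB-453 shared 1317 genes higher in both, where independent lists would share 726 (adjusted p = 2.95e-180). They shared 1726 lower in both against 834 (adjusted p = 2.40e-299, from a p floored at 1e-300). MCF7 and MDA-MB-468 shared 72 higher against 52.1 (adjusted p = 0.00672) and 50 lower against 63.1. A further 104 genes were higher in MCF7 and lower in MDA-MB-468 against 59.4 (adjusted p = 2.86e-09). MDA-MB-453 and MDA-MB-468 shared 82 higher against 61.5 (adjusted p = 0.00672) and 69 lower against 70.95. With the replicate block, over 12 overlaps, MCF7 and MDA-MB-468 shared 562 higher against 445 (adjusted p = 6.42e-12), 379 lower against 456, and 601 higher in MCF7 and lower in MDA-MB-468 against 436 (adjusted p = 1.67e-22). MDA-MB-453 and MDA-MB-468 then shared 587 higher against 475 (adjusted p = 3.17e-11) and 515 lower against 474 (adjusted p = 0.0135), the latter excess seen only with the block. Across genes, which are not independent replicates, log2 fold changes of MCF7 correlated with those of MDA-MB-453 (Pearson r = 0.45), of MCF7 shRB1-3 (r = 0.54) and hardly with those of MDA-MB-468 (r = 0.00928). Of the 5689 MCF7 calls tested in MCF7 shRB1-3, 80.6% had the same sign there. The median there was 0.30 against 0.74 for the genes higher in MCF7, and -0.26 against -0.57 for those lower.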

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

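All the tests of patterns below, and the counts of other splits, were chosen only after the results were seen, the differences between lines before. In the 4 differences between cell lines the interaction of line and treatment passed its test, by edgeR for panel genes and by camera for lists, with no control shared between lines. Values are differences of log2 fold changes ± SE or, for lists, the median difference. Each gene named had padj, and each list a camera adjusted p, under 0.05.

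For MDA-MB-468 minus MCF7 the drug effects of the panel genes differed for RB1 (0.68 ± 0.18), CDK4 (0.68 ± 0.14), CDK6 (-1.79 ± 0.35), CCND1 (-1.07 ± 0.22) and CCNE2 (1.43 ± 0.33). They also differed for E2F1 (1.43 ± 0.17), MCM2 (1.26 ± 0.13), MKI67 (1.21 ± 0.26), CDKN1A (1.45 ± 0.26) and DNMT1 (0.98 ± 0.22). Further such genes were FOSL2 (-0.69 ± 0.21), HLA-B (-1.29 ± 0.15) and BCL2L1 (-0.58 ± 0.16). The lists called for this difference, with their medians, were DNA replication (1.204), mitosis (1.21), cyclins, CDKs and the RB pathway (0.67), MHC class I (-0.29) and estrogen receptor targets (-0.58). They were joined by luminal markers (-0.48), basal markers (-1.404), lysosome (-0.53), ribosome biogenesis (0.44) and extracellular matrix (-0.81). The remaining list was mitochondrially encoded genes (0.84). None of these list calls held with an estimated correlation, the smallest adjusted p then being 0.191. Left-out libraries ended calls as follows. FOSL2 had adjusted p = 0.0675 without MCF7 DMSO 1, 0.0539 without MCF7 abemaciclib 3, 0.0812 without MDA-MB-468 DMSO 3 and 0.0636 and 0.0598 without MDA-MB-468 abemaciclib 1 and 2. Extracellular matrix had adjusted p = 0.0505 without MCF7 abemaciclib 3.

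For MDA-MB-468 minus MDA-MB-453 the drug effects of the panel genes differed for CDK4 (0.48 ± 0.11), CCND1 (-0.88 ± 0.23), CCNE1 (2.21 ± 0.32), CCNE2 (5.42 ± 0.19) and E2F1 (2.04 ± 0.16). They also differed for MCM2 (2.86 ± 0.11), MKI67 (7.46 ± 0.55), CDKN1A (1.57 ± 0.26), DNMT1 (1.52 ± 0.16), FOSL2 (-1.17 ± 0.22) and JUN (-1.88 ± 0.51). The lists called for this difference follow with median, camera adjusted p and camera adjusted p with an estimated correlation. They were DNA replication (2.12, 4.49e-83, 2.71e-04), mitosis (4.297, 3.66e-130, 0.00335) and cyclins, CDKs and the RB pathway (1.34, 1.74e-15, 0.00372). Further ones were histones (-1.19, 6.94e-04, 0.649) and DNA methylation and Polycomb (0.52, 3.44e-04, 0.0223). They were joined by luminal markers (-0.84, 0.00341, 0.166), cholesterol synthesis (0.87, 1.68e-06, 0.461), lysosome (-0.64, 2.65e-05, 0.166) and ribosome biogenesis (0.51, 0.0133, 0.77).

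For MDA-MB-453 minus MCF7 the drug effects of the panel genes differed for CDK6 (-2.47 ± 0.79), CCNE1 (-1.86 ± 0.42), CCNE2 (-4.04 ± 0.38), E2F1 (-0.66 ± 0.18) and MCM2 (-1.64 ± 0.13). They also differed for MKI67 (-6.29 ± 0.65), DNMT1 (-0.58 ± 0.18), JUN (1.12 ± 0.27) and BCL2L1 (-0.38 ± 0.10). The lists called for this difference, with their medians, were DNA replication (-0.94), mitosis (-2.96), cyclins, CDKs and the RB pathway (-0.85), histones (1.27) and DNA methylation and Polycomb (-0.58). They were joined by estrogen receptor targets (-0.56), luminal markers (0.26), cholesterol synthesis (-0.90), extracellular matrix (-0.79) and mitochondrially encoded genes (0.57). None of these list calls held with an estimated correlation, the smallest adjusted p then being 0.141. Left-out libraries ended calls as follows. CDK6 had adjusted p = 0.0713 and 0.0717 without MCF7 DMSO 1 and 2, 0.0595, 0.0514 and 0.0766 without MCF7 abemaciclib 1, 2 and 3, 0.0755 and 0.121 without MDA-MB-453 DMSO 1 and 2 and 0.0595 without MDA-MB-453 abemaciclib 2. DNMT1 had adjusted p = 0.0859 and 0.0575 without MCF7 DMSO 1 and 2, 0.0576 without MCF7 abemaciclib 1, 0.0572 and 0.0728 without MDA-MB-453 DMSO 1 and 3 and 0.0778 and 0.0628 without MDA-MB-453 abemaciclib 1 and 2. Estrogen receptor targets had adjusted p = 0.0587 without MCF7 abemaciclib 2 and 0.0666 without MDA-MB-453 abemaciclib 3. Luminal markers had adjusted p = 0.0556 without MCF7 abemaciclib 1 and 0.0614 without MDA-MB-453 abemaciclib 2. With libraries 1 and 2 of MDA-MB-453 summed, CDK6, DNMT1 and BCL2L1 were not called (adjusted p = 0.071, 0.103 and 0.0874), nor the luminal list (0.0544).

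For MCF7 shRB1-3 minus MCF7 the drug effects of the panel genes differed for E2F1 (1.16 ± 0.26) and MCM2 (1.07 ± 0.19). The lists called for this difference, with their medians, were DNA replication (0.86), mitosis (0.83), cyclins, CDKs and the RB pathway (0.50), histones (0.64) and DNA methylation and Polycomb (0.22). They were joined by AP-1 subunits (-0.66), estrogen receptor targets (-0.54), luminal markers (-0.20), basal markers (-0.80) and lysosome (-0.46). The remaining lists were stress response (-0.78), ribosome biogenesis (0.25) and extracellular matrix (-0.46). None of these list calls held with an estimated correlation, the smallest adjusted p then being 0.245. Left-out libraries ended calls as follows. E2F1 and MCM2 lost theirs without single libraries of either line, as given above. Stress response had adjusted p = 0.0758 without MCF7 DMSO 1 and 0.14 without MCF7 abemaciclib 2. Leaving out 1 MCF7 shRB1-3 library keeps 1 in its group, so for lists whose call this ended only the median is given. Without DMSO 2 it was 0.42 for cyclins, CDKs and the RB pathway, 0.29 for DNA methylation and Polycomb and -0.06 for AP-1 subunits. It was -0.08 for estrogen receptor targets, 0.06 for luminal markers, 0.14 for stress response, 0.23 for ribosome biogenesis and -0.18 for extracellular matrix. Without DMSO 1 it was 0.64 for histones, and without abemaciclib 1 -0.45 for stress response.

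The first pattern is in the 35 tested interferon-stimulated genes of MDA-MB-453. In 14, abemaciclib libraries 1 and 2 lay above every DMSO library and over 2 times library 3. Library 3 lay below every DMSO library in 10 of them. The choice forces a high ratio to library 3 (log2 medians 2.51 and 2.11, IFI6 at 95.3, 105 and 8.86 CPM). An untreated library under a treated label is argued against by the mitosis genes, whose median log2 ratio of library 3 to DMSO was -5.07 (upper quartile -3.55). Cells of another of the lines are argued against by genes specific to MCF7 or MDA-MB-468, at most 0.118% of their own line. A day shared by the libraries numbered 3 and acting alike on all cells is argued against over all 35 members, in a test that replaced 1 on those 14, since DMSO library 3 was lower than DMSO libraries 1 and 2 by a median log2 ratio of -0.17 against -1.31 with the drug, the smaller fall in 32 genes. A day or culture effect that needs the drug stays open, since libraries 1 and 2 also lay close to each other, and no biological explanation was tested.

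The second pattern is a histone list median of -0.66 in MCF7 and 0.83 in MDA-MB-453. Neither list call held with an estimated correlation (adjusted p = 0.632 and 0.641), nor the MCF7 call without MCF7 DMSO 2 (0.0567). Reads moved between near-identical copies would leave the sum unchanged, but over 59 histone genes the sum went from 342 ± 47.2 to 997 ± 144 CPM in MDA-MB-453 (of library totals, SD, n = 3), and the lowest treated library was 2.299 times the highest DMSO library. In MCF7 the sum went from 239 ± 54.3 to 192 ± 39.4 CPM, with overlapping libraries. More RNA without a poly(A) tail in treated MDA-MB-453 and a change of histone expression in this line cannot be told apart, since 6 histone genes were called lower there while 18 rose, and 0 symbols of small nuclear, small nucleolar, 7SL, 7SK or Y RNA genes are in that line's table.

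The third pattern is the size of the differences between MCF7 shRB1-3 and MCF7 in DMSO, where 184 genes were called at least 8-fold apart and 71 of them (38.6%) had 3 counts or fewer in one table, such as EIF4A1, coding for a translation initiation factor, with 96367 counts in MCF7 and 0 in MCF7 shRB1-3. A candidate explanation is a different annotation or counting of overlapping genes. Of those found in the gene models, 23 of 67 (34.3%) share at least 50% of their exonic bases with another gene, against 2.23% of the other tested genes (Fisher's exact test, one-sided, p = 5.40e-21). For the remaining 113 genes, the hairpin and a drift of the cells cannot be told apart from table and batch. This test replaced 2 earlier ones that decided nothing.

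Other splits of the same libraries were counted for each result with 3 libraries per group. In MCF7, MDA-MB-453 and MDA-MB-468 the real split was the 1 of 10 with as many genes (5942, 7024 and 599, the highest other split giving 0 by edgeR in each), and 10 splits are too few for a share under 0.05. For the differences between lines, labels were exchanged within each line, which also ends the drug effect of a line, so these splits cannot exclude chance as the source of a difference. Of 60 splits 1 gave as many genes for MDA-MB-468 minus MCF7 (3908, highest other 3296), 1 for MDA-MB-468 minus MDA-MB-453 (4875, highest other 4492) and 2 for MDA-MB-453 minus MCF7 (4304, highest other 4377). Each of these highest other splits kept or exchanged all labels of 1 line.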

How the results depend on the processing

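The sum of MDA-MB-453 libraries 1 and 2 and the removal of genes with 3 counts or fewer in either table were chosen only after the results were seen, the other alternatives before. Of 232 values of named genes 162 kept their direction and side of the threshold under every alternative run, and of 196 list results 72 did. With a log2 fold change of at least 1 required, the counts were 1667 in MCF7, 2020 in MDA-MB-453, 250 in MDA-MB-468, 1654 for MDA-MB-468 minus MCF7, 2091 for MDA-MB-468 minus MDA-MB-453 and 1827 for MDA-MB-453 minus MCF7, since fewer genes can pass 2 conditions than 1. Shared calls were then 176 higher and 324 lower for MCF7 and MDA-MB-453, 17 and 5 for MCF7 and MDA-MB-468, and 9 and 16 for MDA-MB-453 and MDA-MB-468. DESeq2 called 1266 genes in MDA-MB-468, 64 in MCF7 shRB1-3, 945 for MCF7 shRB1-3 minus MCF7 and 1065 between MCF7 shRB1-3 and MCF7 in DMSO. The cause was not tested. In simulation 13.0%, 15.5%, 16.8% and 30.2% of DESeq2 calls in MCF7, MDA-MB-453, MDA-MB-468 and MCF7 shRB1-3 were false. By edgeR these shares were 5.9%, 3.4%, 8% and 36.7%. With the replicate block the counts were 3263 in MDA-MB-468, 269 in MCF7 shRB1-3, 6060 for MDA-MB-468 minus MCF7 and 791 for MCF7 shRB1-3 minus MCF7. Replicate effects were built into the simulation, so it cannot judge these counts. In 1 fit of all 18 libraries MDA-MB-468 had 1611 calls, and without a filter MCF7 shRB1-3 had 21, and the cause was not tested. That joint fit ended the calls of DDIT4, SLC3A2 and TRIB3 in MDA-MB-468 (adjusted p = 0.212, 0.276 and 0.109) and of CDK4 and CDKN1A in MDA-MB-453 (0.122 and 0.304). No filter ended those of COL13A1, OLFML3 and IL8 in MDA-MB-468 (adjusted p = 0.0597, 0.0575 and 0.0529).

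Leaving out 1 library at a time gave between 4622 and 6581 genes in MCF7, 6064 and 7711 in MDA-MB-453, 8 and 1413 in MDA-MB-468, 0 and 4145 in MCF7 shRB1-3, 2972 and 4670 for MDA-MB-468 minus MCF7, 4250 and 5518 for MDA-MB-468 minus MDA-MB-453, 3614 and 4827 for MDA-MB-453 minus MCF7, 14 and 2103 for MCF7 shRB1-3 minus MCF7, and 215 and 3187 between MCF7 shRB1-3 and MCF7 in DMSO. Called lists then ranged from 5 to 14 for MCF7 shRB1-3 minus MCF7 and from 0 to 10 for the DMSO comparison. In MCF7 shRB1-3 CCNE2 ranged from -0.73 to 0.90, a change of direction. The lone DMSO library is there assumed to vary like the other group. MDA-MB-453 with libraries 1 and 2 summed called 5114 genes, having fewer samples.

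With an estimated correlation the called lists were 2 in MDA-MB-453, 4 for MDA-MB-468 minus MDA-MB-453 and 0 in each other comparison. With fry they were 16 in MDA-MB-453, 2 in MDA-MB-468, 0 in MCF7 shRB1-3, 2 for MCF7 shRB1-3 minus MCF7 and 0 in the DMSO comparison, against 9, 7, 7, 13 and 2 with camera, and the cause was not tested. Depth limits genes of few counts most, the least deep library being MCF7 shRB1-3 DMSO 1 with 8413314 counts.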

Other observations

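No hypothesis was tested in this part and no test was added for it. Of the receptor tyrosine kinases and adaptors in MDA-MB-453 9 of 19 tested rose, 4 fell and 6 were not called (9 rose and 4 fell adjusted over the list alone, median 0.20, camera adjusted p = 0.155, fry 0.00295). ERBB2, the receptor gene amplified in this line, rose from 1180 to 2416 CPM (1.03 ± 0.08, padj = 5.28e-06) and DDR1, a collagen receptor, from 347 to 765 CPM (1.14 ± 0.06, padj = 7.71e-07). FGFR2, a fibroblast growth factor receptor, fell there (-3.401 ± 0.40, padj = 1.02e-04) and rose in MCF7 (0.95 ± 0.22, padj = 0.00626). In MCF7 9 of 22 tested rose, 6 fell and 7 were not called (camera adjusted p = 0.579, fry 0.024), and IRS2, an adaptor of insulin signalling, fell (-1.48 ± 0.25, padj = 0.00131). In MDA-MB-468 0 of 23 tested rose, 2 fell and 21 were not called (2 and 7 with the block, camera adjusted p = 0.0969, 0.0287 without DMSO 2 and 0.049 without abemaciclib 3). INSR, the insulin receptor gene, fell from 107 to 47.8 CPM (-1.17 ± 0.15, padj = 0.0116, adjusted p = 0.0678 and 0.0549 without MDA-MB-468 DMSO 2 and 3).

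Of the p53 targets, in MCF7 5 of 28 tested rose, 8 fell and 15 were not called (camera adjusted p = 0.391). In MDA-MB-453 8 of 25 tested rose, 11 fell and 6 were not called (camera adjusted p = 0.993, fry 0.0371) and in MDA-MB-468 3 of 26 tested rose, 0 fell and 23 were not called (7 and 2 with the block, camera adjusted p = 0.334). DDB2, a DNA damage recognition gene, fell in MCF7 (-1.54 ± 0.12, padj = 1.44e-05) and MDA-MB-453 (-1.41 ± 0.12, padj = 9.69e-06). Of the BCL2 family 6 of 15 tested rose, 4 fell and 5 were not called in MCF7 (camera adjusted p = 0.349, fry 0.0104). The pro-apoptotic gene BID rose there (1.48 ± 0.09, padj = 3.01e-06). In MDA-MB-453 4 of 13 tested rose, 4 fell and 5 were not called of that family (camera adjusted p = 0.997). MCL1, a survival gene, rose there from 201 to 361 CPM (0.84 ± 0.08, padj = 3.08e-05) and BCL2 fell (-2.16 ± 0.34, padj = 5.76e-04). Of the secreted inflammatory factors 8 of 16 tested rose, 3 fell and 5 were not called in MCF7 (camera adjusted p = 0.412, fry 0.022), with LIF, a cytokine, at 3.37 ± 0.37, padj = 7.63e-05.

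Markers of other cell types were low, here in CPM of library totals without TMM. The median over the fibroblast markers was at most 0.107 CPM in any group, over the leukocyte markers at most 0.0185 CPM and over the endothelial markers at most 0.436 CPM. The highest single genes were COL1A1, a collagen, at 132 CPM in MDA-MB-453 DMSO, CD14 at 30.7 CPM in MDA-MB-468 DMSO and ERG at 9.497 CPM in MCF7 shRB1-3 with abemaciclib.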
